A study of Arabidopsis thaliana with 40 samples.

How the data were processed

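The deposited files of 20 2-colour Agilent arrays were used, each of which is deposited under 2 samples, 1 per dye. Each array gave 1 Col-0 and 1 elp2 sample. Per the file headers and the submitters' processing notes, the images were read with Agilent Feature Extraction 10.1.1.1, and the values used here are the mean spot intensity and the median local background intensity of each dye on a linear scale, with the program's own flags for outlier spots and for spots well above background. The processed signals, also an intensity, were background subtracted and dye normalized by that program, per the file headers, and served as an alternative. The deposited series matrix holds log2 values, a scale read from the values themselves, and its columns have nearly the same distribution, with medians from 9.00 to 9.01. No note records how they were normalized. Only 2 of its 40 columns correlated best with the channel of their own label, over 16830 probes, and 35 correlated best with a channel of another condition or genotype. The columns matched 40 different channels best (r from 0.942 to 0.989), as the same channels in another order would. ELP2 was lower in elp2 on 20 of 20 arrays, which argues against wrong genotype labels in the array files. Condition labels stay open. No column was moved, and the matrix was used for this check alone.

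Spot intensities were corrected with limma 3.58.1 (normexp, offset 50), normalized within arrays by loess with control spots at weight 0 and between arrays by the Aquantile method, and split into the 2 channels as log2 intensities. Spots marked as outliers were left out, and repeated spots of a probe were averaged. Of 43603 probes, 38413 carry a locus in the file annotation, and the other 5190 were left out. At each of 29030 loci the probe with the highest mean was kept, and genes were kept when well above background in each sample of at least 1 group, which left 21010 tested genes. Symbols came from the RefSeq table of the TAIR10.1 annotation, which names 28595 of these loci. The number of spots well above background, 63.6% to 72.4% per channel, limits which genes can be measured, and 0 to 20 spots per channel were saturated.

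A model with 14 group means and a dye term was fitted with limma, with the array as a block (intraspot correlation 0.279) and moderated with a trend and robust settings. In each of 28 contrasts p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The contrasts compared elp2 with Col-0 in each condition and on average, each time and wounding with 0 h, inoculated with wounded leaves at 3 h, and the responses of the genotypes with each other. The 27 gene lists were written from general knowledge before the data were opened and hold 354 members, of which 353 have a probe. They were tested with camera at a preset correlation of 0.01, adjusted over 756 pairs of list and contrast. An estimated correlation and fry, a rotation test, served as alternatives. The size of the elp2 response relative to Col-0 came from regressing the difference of the 2 responses on their mean.

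The rule for named genes was ELP2 and the other Elongator subunits, up to 4 members of each described list with the smallest p, and the 5 highest and 5 lowest called genes with a symbol that were well above background in each sample of the brighter group and, between genotypes, had the same sign on each array. This rule, the comparisons, the tests, the lists and the alternatives below were chosen before the data were examined. These were the processed signals less their 75th percentile, quantile normalization of the 40 channels, other filters on dim probes, fits without the dye term, without the array block or with the compared groups alone, slide as a block, the replicate number as a block and single samples left out. Fits within slides, with slide as a random block and with pairing by array at 0 h were added later, as were list tests with slide as a block or no array block.

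Slides were read from the file headers. With 4 arrays on each of 5 slides, slide could be a fixed block in 18 of 28 contrasts. From 3 h on, the same replicate number in the labels of Col-0 and elp2 marks the same array. The pairs correlated, in residuals of a fit without block, with r over 0.1 in 14 of 18 cases, and in each of the 3 pairs at 12, 24 and 48 h.

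The fits were tested on simulated data with the design of this study. For elp2 minus Col-0 at 6 h, 60 of 67 genes changed 1.5-fold were called, 65 of 67 changed 2-fold, and 8 of 20810 unchanged genes. At 0 h, 52 of 67 changed 1.5-fold were called. A shifted list was called and 1 of 27 unshifted lists was called, and a response ratio of 0.8 was returned as 0.804 to 0.811. Simulated genes varied independently of each other, so these list calls do not test the preset correlation, on which most real list calls rest. R 4.3.3, data.table (1.17.8), statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.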

Results

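Gene expression was measured in leaves of Arabidopsis thaliana Col-0, the wild type, and of an elp2 mutant after inoculation with Botrytis cinerea, a necrotrophic fungus that kills plant tissue and feeds on it. ELP2 is a subunit of Elongator, a complex that works with RNA polymerase II during transcript elongation. The 40 samples fell into 14 groups, Col-0 and elp2 leaves at 0 h of infection, at 5 later times (3, 6, 12, 24 and 48 h) and 3 h after wounding without the fungus. There were 3 samples per group, except for 2 per group at 0 h. Each of the 20 dual-channel arrays carried 1 Col-0 and 1 elp2 sample of the same condition in opposite dyes. Median signals of the 40 channels ran from 213 to 602, and 63.6% to 72.4% of spots were well above background. The number of arrays limits the precision of the values. Samples of 1 group correlated across 20444 genes with r from 0.987 to 0.998, against a median of 0.934 between samples of different groups. The labels call the samples biological replicates but also speak of equal amounts of RNA from the replicates, which may mean pooling, so p-values may measure only technical spread. Changes below are log2 differences ± standard error from the limma fit over 21010 genes. Genes said to have risen or fallen, or to have been higher or lower, passed adjusted p 0.05. For genes not well above background in any sample of 1 group, a lower bound is given as at least N-fold. Genes called highest or lowest are among those with a symbol and well above background in each sample of the brighter group.

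ELP2 (AT1G49540) was examined first, in every sample. On 20 of 20 arrays its signal was lower in the elp2 sample than in the Col-0 sample. Single samples ran from 10.13 to 11.80 log2 units in Col-0 and from 9.81 to 10.69 in elp2. The Col-0 group means were 10.26 ± 0.18 (SD, n = 2) at 0 h, 11.51 ± 0.30 (SD, n = 3) at 3 h, 11.71 ± 0.12 at 6 h, 11.22 ± 0.31 at 12 h, 11.65 ± 0.13 at 24 h, 11.45 ± 0.12 at 48 h and 11.35 ± 0.19 after wounding. In the same order the elp2 means were 9.84 ± 0.04, 10.13 ± 0.20, 10.05 ± 0.10, 10.18 ± 0.18, 10.18 ± 0.05, 10.41 ± 0.24 and 10.11 ± 0.05. The genotype difference did not pass at 0 h, with 2 samples per genotype (-0.42 ± 0.16, not passing), and passed in each later condition, from -1.07 ± 0.13 at 48 h to -1.69 ± 0.13 at 6 h. The probe lies on chromosome 1 from 18337440 to 18337499 in the older build named in the array files. The labels do not name the mutant allele, so it is not known whether the probe lies before or after the mutated part, and the signal left in elp2 is no measure of the protein. Of the other subunits of Elongator, ELP3, the histone acetyltransferase, was lower at 3, 6, 24 and 48 h (-0.27 ± 0.06 at 6 h and -0.31 ± 0.06 at 48 h), and ELP4 was lower at 6 h (-0.16 ± 0.05) and 24 h (-0.17 ± 0.05). The 6-member list passed at 24 h (ELP2, ELP3 and ELP4 lower, 3 not passing). With 3 lower adjusted over the list alone, the median was -0.14 (camera adjusted p = 0.0448, and adjusted p = 0.371 with an estimated correlation). With the replicate number as a block that call was lost (adjusted p = 0.0802), as it was with slide as a block (adjusted p = 0.0563).

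**Figure D1:**
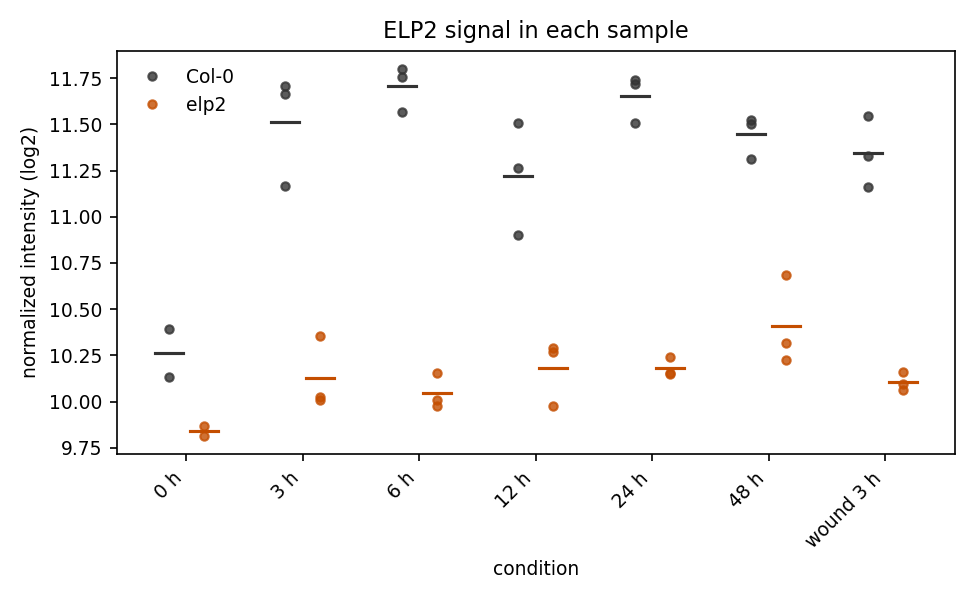
ELP2 signal (normalized log2 intensity) in each of the 40 samples, by condition, for Col-0 and elp2; points are samples and horizontal bars are group means of 3 samples (2 at 0 h). The elp2 samples lie between 9.81 and 10.69, and the Col-0 samples of the 6 conditions other than 0 h lie at or above 10.90.

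Many defence genes of Col-0 differed between leaves 3 h after wounding and 0 h leaves. No unwounded leaves were taken at 3 h, so hour of day, handling and slide differed along with the wound. The highest rises from 0 h were those of MLO12 (5.80 ± 0.27), IGMT2 (5.59 ± 0.21), IGMT3 (5.57 ± 0.32), CYP81F2 (5.46 ± 0.26) and WRKY30 (5.29 ± 0.34, well above background in 1 of 2 0 h samples), of which CYP81F2 and the IGMT methyltransferases modify indole glucosinolates. The wax biosynthesis gene CER1 (-4.56 ± 0.60) and the cold-regulated gene COR15B (-3.39 ± 0.25) fell, as did BGLU47 (-3.51 ± 0.18), PCC1 (-3.41 ± 0.54) and THI2.2 (-3.25 ± 0.25). Among WRKY factors, regulators of defence genes, 19 of 20 members rose and 1 fell, with WRKY53 (4.52 ± 0.22) and WRKY28 (2.73 ± 0.14) among the risers. A median of 1.82 gave camera adjusted p = 2.6e-13, and adjusted p = 0.0144 with an estimated correlation, with 19 higher and 1 lower adjusted over the list alone. In the pattern recognition list, the kinase genes BIK1 (2.60 ± 0.10), FRK1 (4.65 ± 0.26) and MPK3 (1.84 ± 0.12) rose (20 of 24 members rose and 4 did not pass). At median 1.17, camera gave adjusted p = 1.4e-11 (adjusted p = 0.0835 with an estimated correlation), and 22 higher were counted adjusted over the list alone. Ethylene receptor genes and their regulators ETR2 (2.28 ± 0.14), ERS1 (1.56 ± 0.11) and EBF2 (1.5 ± 0.09) rose with most of their list, in which 10 of 12 members rose and 2 did not pass. Adjusted over the list alone, 10 higher passed, around a median of 1.42 (camera adjusted p = 1.8e-06, adjusted p = 0.0336 with an estimated correlation). The aliphatic glucosinolate regulator MYB29 (-1.75 ± 0.20) fell with 11 others of 13 list members. The median was -1.2, with 12 lower adjusted over the list alone (camera adjusted p = 5.1e-05, adjusted p = 0.327 with an estimated correlation). In all, 10802 genes passed in Col-0 (5056 rose and 5746 fell; 2218 by 2-fold or more) and 10077 in elp2 (4623 and 5454). In elp2 the rises of GSTF6 (5.95 ± 0.26), GSTF7 (5.36 ± 0.25), IGMT2 (5.18 ± 0.21) and CYP81F2 (4.60 ± 0.26) were among those that passed, and the CER1 (-3.46 ± 0.60) and NEET (-3.43 ± 0.78) transcripts fell. With slide as a random block the counts were 9993 and 9260.

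At 3 h after inoculation, Col-0 leaves had raised genes of camalexin, the main phytoalexin of Arabidopsis, and of detoxification. The rises of PAD3 (6.33 ± 0.47), GSTF6 (5.82 ± 0.26) and CYP71A12 (at least 18.0-fold) were among the highest, where PAD3 and CYP71A12 are camalexin enzymes, and YLS9 (5.88 ± 0.30, well above background in 1 of 2 0 h samples), AACT1 (5.75 ± 0.43) and GSTF7 (5.55 ± 0.25) rose by similar amounts. In the tryptophan and camalexin list 11 of 13 members rose and 2 did not pass. With 11 higher adjusted over the list alone, the median was 1.52 (camera adjusted p = 6.1e-07, and adjusted p = 0.209 with an estimated correlation). The detoxification list held CYP81D8 (3.84 ± 0.25) and UGT73B3 (3.84 ± 0.28), and 19 of 22 members rose and 3 did not pass. A median of 1.97 gave camera adjusted p = 5.0e-10, and adjusted p = 0.228 with an estimated correlation, with 20 higher adjusted over the list alone. Of the WRKY factors 17 of 20 members rose, 1 fell and 2 did not pass, among them WRKY53 (4.36 ± 0.22) and WRKY15 (2.15 ± 0.12). At median 1.83, camera gave adjusted p = 1.3e-10 (adjusted p = 0.0287 with an estimated correlation), and 17 higher and 1 lower were counted adjusted over the list alone. Cell division genes went down, KNOLLE (-1.11 ± 0.12) and CYCB1;2 (-0.78 ± 0.12) among them (9 of 10 members fell and 1 did not pass). Adjusted over the list alone, 9 lower passed, around a median of -0.81 (camera adjusted p = 3.9e-04, adjusted p = 0.248 with an estimated correlation). The wax gene CER1 (-3.88 ± 0.60) and THI2.2 (-3.34 ± 0.25), LEA3 (-3.04 ± 0.25), BGLU47 (-2.95 ± 0.18) and COR15B (-2.94 ± 0.25) fell. The elp2 leaves at 3 h raised NATA1 (6.34 ± 0.46), GSTF6 (6.23 ± 0.26), RNS1 (5.80 ± 0.40) and PAD3 (5.31 ± 0.47, well above background in 1 of 2 0 h samples), and their jasmonate (JA) synthesis list rose: 12 of 13 members rose and 1 fell, with AOC1 (2.77 ± 0.25), AOC2 (1.72 ± 0.18) and AOS (1.59 ± 0.18). The median was 1.59, with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.6e-07, adjusted p = 0.178 with an estimated correlation). In Col-0 the same list did not pass as a set at 3 h (6 of 13 members rose, 2 fell and 5 did not pass, median 0.40, camera adjusted p = 0.0684). Over all genes, 11075 passed in Col-0 (4995 rose, 6080 fell) and 9807 in elp2 (4467 rose, 5340 fell). With slide as a block the Col-0 count was 11080, and within the slide that held both times it was 9339.

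By 6 h the acyltransferase gene AACT1 (7.69 ± 0.43), PAD3 (7.59 ± 0.47) and the oxygenase gene DIN11 (7.49 ± 0.56) led the rises in Col-0. All 11 measured evening genes of the circadian clock rose, with PRR3 (2.21 ± 0.12), FKF1 (1.92 ± 0.10) and LUX (1.88 ± 0.11), and all 5 morning genes fell, with CCA1 (-2.86 ± 0.14) and RVE1 (-1.97 ± 0.19). For the evening list, 11 were higher adjusted over the list alone (median 1.54, camera adjusted p = 9.4e-07, adjusted p = 0.00572 with an estimated correlation). For the morning list, 5 were lower adjusted over the list alone (median -1.36, camera adjusted p = 0.00151, adjusted p = 0.205 with an estimated correlation). Detoxification genes GSTF7 (6.78 ± 0.25), GSTU4 (6.13 ± 0.34) and UGT73B3 (4.62 ± 0.28) rose (20 of 22 members rose and 2 did not pass). With 20 higher adjusted over the list alone, the median was 2.85 (camera adjusted p = 1.5e-09, and adjusted p = 0.232 with an estimated correlation). In the camalexin list 11 of 13 members rose and 2 did not pass, including the tryptophan synthase gene TSA1 (AT3G54640, 3.12 ± 0.16). A median of 2.41 gave camera adjusted p = 1.2e-06, and adjusted p = 0.219 with an estimated correlation, with 11 higher adjusted over the list alone. The chalcone synthase gene CHS (-3.53 ± 0.32), LEA3 (-3.68 ± 0.25), COL2 (-3.94 ± 0.15) and AFR (-3.94 ± 0.24) and THI2.2 (-4.33 ± 0.25, well above background in 1 of 3 6 h samples) had the lowest changes. In elp2 at 6 h, GSTF6 (6.26 ± 0.26), PAD3 (6.05 ± 0.47, well above background in 1 of 2 0 h samples) and DIN11 (5.83 ± 0.56, well above background in 1 of 2 0 h samples) rose and LEA3 (-5.29 ± 0.25), PHI-1 (-4.72 ± 0.45) and TCH4 (-4.04 ± 0.50) fell; its evening clock list rose as well (10 of 11 members rose and 1 fell). At median 1.17, camera gave adjusted p = 1.1e-06 (adjusted p = 0.00572 with an estimated correlation), and 10 higher and 1 lower were counted adjusted over the list alone. The counts were 13559 in Col-0 (6667 rose, 6892 fell) and 11124 in elp2 (5399 rose, 5725 fell). Modelling slide gave 11639 and 8625; no slide held both times. With the processed signals the median change of all genes in Col-0 differed by -0.12 log2 units.

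At 12 h photosynthesis genes had fallen in Col-0 from their 0 h level, again without uninoculated leaves at that time. The light-harvesting genes LHCB2.3 (-7.18 ± 0.34) and LHCB2.1 (-5.51 ± 0.14) and the photosystem I genes PSAH2 (-3.78 ± 0.12) and PSAD2 (-3.08 ± 0.13) were among them, and of 33 nuclear-encoded members 30 fell and 3 did not pass. Adjusted over the list alone, 30 lower passed, around a median of -1.68 (camera adjusted p = 6.9e-13, adjusted p = 0.108 with an estimated correlation). The camalexin list rose as a whole, with TSA1 (4.87 ± 0.16) and PAT1 (2.80 ± 0.11), ASA1 (3.66 ± 0.17) and GSTF6 (6.38 ± 0.26), which act in tryptophan supply and glutathione conjugation (13 of 13 members rose). The median was 3.56, with 13 higher adjusted over the list alone (camera adjusted p = 3.8e-09, adjusted p = 0.143 with an estimated correlation). The highest rises were those of AACT1 (9.25 ± 0.43), DIN11 (8.94 ± 0.56) and PAD3 (8.63 ± 0.47), followed by PXMT1 (at least 176-fold) and TPX2 (7.34 ± 0.30, well above background in 1 of 2 0 h samples). Defensin and chitinase genes under JA and ethylene control, PDF1.1 (at least 129.9-fold), PR4 (5.37 ± 0.32) and PDF1.2C (4.83 ± 0.48), rose (7 of 8 members rose and 1 did not pass). With 7 higher adjusted over the list alone, the median was 4.77 (camera adjusted p = 0.00126, and adjusted p = 0.223 with an estimated correlation). The aliphatic glucosinolate genes MYB29 (-3.40 ± 0.20) and CYP79F1 (-2.59 ± 0.24) fell (10 of 13 members fell, 1 rose and 2 did not pass). A median of -1.65 gave camera adjusted p = 0.00175, and adjusted p = 0.432 with an estimated correlation, with 10 lower and 1 higher adjusted over the list alone. Anthocyanin genes such as F3H (at least 6.96-fold) and CHS (at least 10.00-fold) fell by the bounds given while TT19, a glutathione transferase of that pathway, rose (2.86 ± 0.22, though another probe gave -1.03, not passing); in this list 9 of 13 members fell, 2 rose and 2 did not pass. At median -0.58, camera gave adjusted p = 0.0324 (adjusted p = 0.496 with an estimated correlation), and 9 lower and 2 higher were counted adjusted over the list alone. In elp2 the photosynthesis list fell too, with LHCB2.3 (-7.08 ± 0.34) and LHCB2.1 (-5.28 ± 0.14), and 27 of 33 members fell, 3 rose and 3 did not pass. Adjusted over the list alone, 27 lower and 3 higher passed, around a median of -0.83 (camera adjusted p = 3.6e-07, adjusted p = 0.228 with an estimated correlation). Genes of the abscisic acid response fell in elp2, with COR15A (-4.74 ± 0.33) and RD22 (-1.77 ± 0.19), and 8 of 13 members fell, 3 rose and 2 did not pass. RAB18 fell by 1 probe (-2.34 ± 0.25) and rose by another (1.28). The median was -0.97, with 8 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.0466, adjusted p = 0.506 with an estimated correlation). The counts were 13862 in Col-0 (7327 rose, 6535 fell) and 13102 in elp2 (6595 rose, 6507 fell).

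Plant defensin genes were among the highest risers at 24 h. In Col-0 PDF1.2C (10.05 ± 0.48), PDF1.2B (10.03 ± 0.52), PDF1.3 (9.93 ± 0.53) and PDF1.2A (9.62 ± 0.49) rose, 4 genes whose near-identical sequences may share signal between probes, and the ethylene response factor genes ORA59 (6.44 ± 0.35), ERF1 (5.32 ± 0.26) and ERF96 (at least 26.3-fold), regulators of such defensins, rose with them. Of the JA and ethylene defence outputs 7 rose and 1 did not pass. With 7 higher adjusted over the list alone, the median was 8.24 (camera adjusted p = 7.3e-06, and adjusted p = 0.108 with an estimated correlation). Of the ERF list 8 rose, 1 fell and 4 did not pass. A median of 1.38 gave camera adjusted p = 0.00403, and adjusted p = 0.422 with an estimated correlation, with 8 higher and 1 lower adjusted over the list alone. JAZ repressors of JA signalling, JAZ8 (4.34 ± 0.29), JAZ10 (2.47 ± 0.28) and JAZ1 (1.71 ± 0.21), rose (7 of 11 members rose, 1 fell and 3 did not pass). At median 1.41, camera gave adjusted p = 0.0334 (adjusted p = 0.504 with an estimated correlation), and 7 higher and 1 lower were counted adjusted over the list alone. Evening clock genes lay below their 0 h level, with GI (-1.80 ± 0.07), PRR5 (-2.93 ± 0.13) and GRP7 (-3.52 ± 0.15), and 9 of 11 members fell, 1 rose and 1 did not pass. Adjusted over the list alone, 9 lower and 1 higher passed, around a median of -1.73 (camera adjusted p = 2.5e-04, adjusted p = 0.0306 with an estimated correlation). Markers of other leaf cell types went down: vascular genes XCP2 (-2.00 ± 0.24) and SUC2 (-0.93 ± 0.14) (7 of 7 members fell), guard cell genes TGG1 (-2.17 ± 0.23) and MYB60 (-1.14 ± 0.13) (8 of 8 members fell) and epidermal genes PDF2 (-2.38 ± 0.13) and LTP1 (-2.36 ± 0.19) (8 of 10 members fell and 2 rose). For these 3 lists in turn, 7, 8 and 8 were lower adjusted over the list alone. Camera gave adjusted p = 0.0203, 0.0268 and 0.00948, and adjusted p = 0.235, 0.348 and 0.309 with an estimated correlation. In elp2, AACT1 (at least 493-fold), DIN11 (8.87 ± 0.56, well above background in 1 of 2 0 h samples), NATA1 (8.22 ± 0.49) and PDF1.2C (8.08 ± 0.48) rose and COR15B (-5.68 ± 0.25), CER1 (-5.01 ± 0.60) and NEET (-4.34 ± 0.78) fell. Its defence outputs rose (8 of 8 members rose). The median was 7.07, with 8 higher adjusted over the list alone (camera adjusted p = 6.1e-07, adjusted p = 0.0757 with an estimated correlation). The counts were 15213 in Col-0 (6995 rose, 8218 fell) and 13944 in elp2 (6253 rose, 7691 fell).

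The defensin rise was still present at 48 h, when the osmotin gene OSM34 (at least 471-fold) joined PDF1.2B (10.29 ± 0.48), PDF1.2C (10.16 ± 0.48) and PR3 (6.31 ± 0.24) in Col-0. Senescence genes rose, among them SAG13 (6.15 ± 0.33), SEN1 (3.88 ± 0.30), NAC092 (3.99 ± 0.24) and NAP (3.12 ± 0.19), of which NAP and NAC092 are regulators of leaf senescence (8 of 9 members rose and 1 did not pass). With 8 higher adjusted over the list alone, the median was 2.79 (camera adjusted p = 9.3e-05, and adjusted p = 0.143 with an estimated correlation). Auxin genes parted: GH3.3 (3.79 ± 0.30) and GH3.5 (1.68 ± 0.16), which conjugate auxin, rose, while IAA3 (-2.53 ± 0.18) and IAA1 (-1.47 ± 0.12) fell (7 of 9 members fell and 2 rose). A median of -1.79 gave camera adjusted p = 0.0339, and adjusted p = 0.456 with an estimated correlation, with 7 lower and 2 higher adjusted over the list alone. Lignin genes CAD5 (2.80 ± 0.17) and F5H1 (1.62 ± 0.15) rose (7 of 12 members rose, 1 fell and 4 did not pass). At median 0.68, camera gave adjusted p = 0.0349 (adjusted p = 0.504 with an estimated correlation), and 7 higher and 1 lower were counted adjusted over the list alone. The cold- and drought-regulated genes COR15B (-6.01 ± 0.25), KIN2 (-5.43 ± 0.36) and KIN1 (-5.18 ± 0.33) and CER1 (-6.17 ± 0.60, well above background in 2 of 3 48 h samples) and PCC1 (-4.73 ± 0.54) fell. In elp2 the protease inhibitor genes UPI (at least 598-fold) and KTI1 (at least 582-fold), the nitrilase gene NIT2 (9.05 ± 0.68, well above background in 1 of 2 0 h samples) and OSM34 (at least 436-fold) had the highest rises, and CER1 (-6.71 ± 0.60), COR15B (-5.75 ± 0.25) and OEP6 (-4.73 ± 0.19) fell. Its detoxification list rose (20 of 22 members rose, 1 fell and 1 did not pass), with GSTF7 (5.92 ± 0.25) and GSTF2 (5.00 ± 0.27). The median was 4.36, with 20 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.5e-11, adjusted p = 0.216 with an estimated correlation). The counts were 13841 in Col-0 (7062 rose, 6779 fell) and 13699 in elp2 (6429 rose, 7270 fell). Leaves at 12, 24 and 48 h cannot be linked to 0 h through shared slides. With slide as a random block, the Col-0 counts at these times were 13315, 14739 and 13300.

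**Figure D2:**
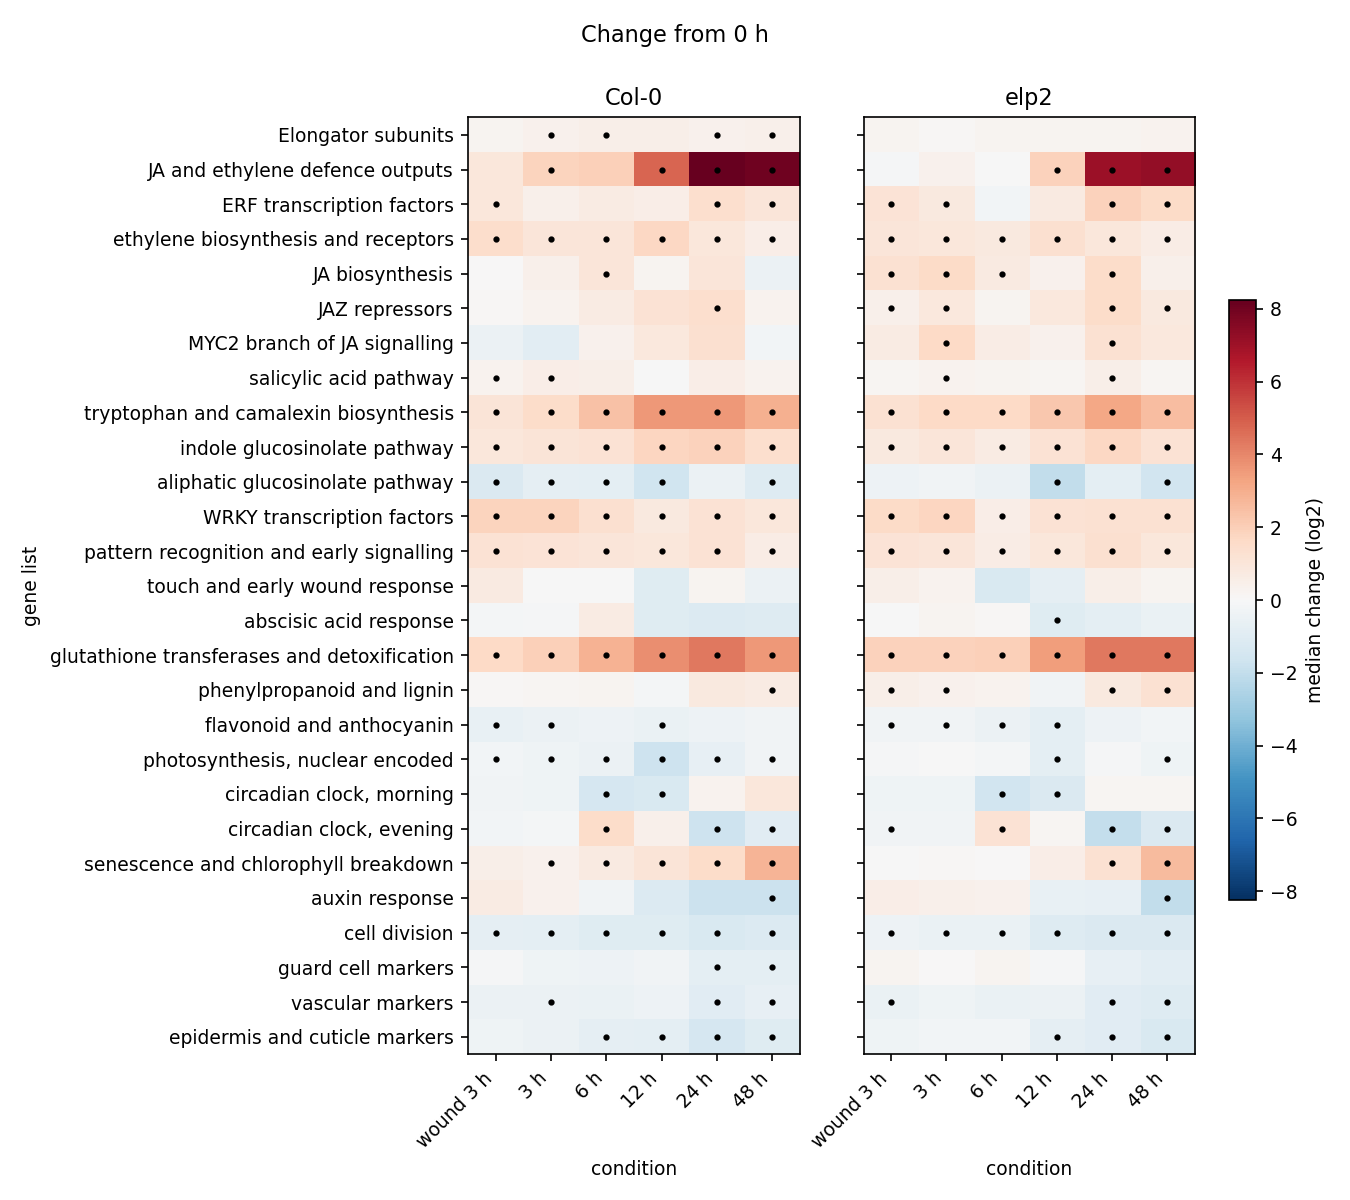
Median log2 change from 0 h (colour) of the 27 gene lists in Col-0 and elp2 after wounding and at each time after inoculation; a dot marks lists that passed the camera test at adjusted p 0.05 with the preset correlation. The defence output list reaches a median of 8.24 in Col-0 and 7.07 in elp2 at 24 h.

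To separate the fungus from the wound that carried it, inoculated leaves were set against wounded leaves at 3 h. In Col-0 the ferritin gene FER4 (2.79 ± 0.88), the acetyltransferase gene NATA1 (2.27 ± 0.41), RLP40 (2.19 ± 0.34) and PCC1 (2.18 ± 0.49) and the chitinase gene CHI (AT2G43570, 2.59 ± 0.31) were higher in inoculated leaves, and ZAT7 (-1.94 ± 0.33), ERF13 (-1.49 ± 0.48) and PP2-A5 (-1.55 ± 0.22) were lower. Tryptophan and camalexin genes PAT1 (0.68 ± 0.10), IGPS (0.93 ± 0.15) and TSB2 (0.68 ± 0.14) were higher (7 of 13 members were higher and 6 did not pass). The median was 0.54, with 11 higher adjusted over the list alone (camera adjusted p = 8.1e-08, adjusted p = 0.178 with an estimated correlation). Most WRKY genes did not pass, with WRKY22 (-1.08 ± 0.16) and WRKY46 (-1.04 ± 0.20) among those that were lower (5 of 20 members were lower, 1 was higher and 14 did not pass). With 7 lower and 1 higher adjusted over the list alone, the median was -0.23 (camera adjusted p = 6.5e-04, and adjusted p = 0.228 with an estimated correlation). The touch response genes TCH4 (-1.30 ± 0.45) and CML37 (-0.94 ± 0.22) were lower (2 of 11 members were lower and 9 did not pass). A median of -0.63 gave camera adjusted p = 0.00866, and adjusted p = 0.432 with an estimated correlation, with 2 lower adjusted over the list alone. Ethylene receptor genes ERS1 (-0.57 ± 0.10) and ERS2 (-0.66 ± 0.13) were also lower (6 of 12 members were lower and 6 did not pass). At median -0.40, camera gave adjusted p = 0.00322 (adjusted p = 0.188 with an estimated correlation), and 7 lower and 1 higher were counted adjusted over the list alone. In elp2 the higher genes included IGMT5 (2.47 ± 0.43), BSMT1 (2.14 ± 0.59), BT2 (2.04 ± 0.27), RLP40 (2.04 ± 0.34) and NATA1 (1.86 ± 0.41), and MYB77 (-1.11 ± 0.34), IOS1 (-1.11 ± 0.22) and CML23 (-1.07 ± 0.32) were lower. The camalexin list was higher there too, with CYP79B2 (0.90 ± 0.19) and PAT1 (0.75 ± 0.10), and 5 of 13 members were higher and 8 did not pass. The median was 0.42, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.5e-05, adjusted p = 0.273 with an estimated correlation). Senescence genes SAG13 (1.62 ± 0.30) and SEN1 (1.03 ± 0.26) were higher in inoculated elp2 leaves (4 of 9 members were higher and 5 did not pass). The median was 0.48, with 5 higher adjusted over the list alone (camera adjusted p = 1.1e-04, adjusted p = 0.143 with an estimated correlation). The counts were 3381 genes in Col-0 (1797 higher, 1584 lower) and 1327 in elp2 (731 higher, 596 lower), of which 103 and 47 changed by 2-fold or more. These counts were unstable: leaving out single samples gave 1551 to 4133 in Col-0 and 318 to 2343 in elp2, and fits to the compared groups alone 261 and 0. No slide held both treatments, and with slide as a random block the counts were 2162 and 641.

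Genotypes were compared at 0 h, with 2 samples per genotype. The BTB protein gene BT2 (2.64 ± 0.28), the floral regulator gene SEP1 (1.88 ± 0.38), CHS (1.59 ± 0.29) and the sugar transporter gene SWEET15 (1.34 ± 0.40) were higher in elp2, and PCC1 (-2.21 ± 0.51), ACD6 (-2.02 ± 0.21), LURP1 (-1.92 ± 0.42), GSTF2 (-1.70 ± 0.25) and PR4 (-1.69 ± 0.29) were lower, of which ACD6 and LURP1 act in defence. Evening clock genes were higher, with PRR5 (1.06 ± 0.12), LUX (0.60 ± 0.10) and ELF3 (0.38 ± 0.09), and 6 of 11 members were higher and 5 did not pass. With 6 higher adjusted over the list alone, the median was 0.32 (camera adjusted p = 9.2e-07, and adjusted p = 0.00572 with an estimated correlation). Indole glucosinolate genes PEN3 (-0.82 ± 0.14), SOT16 (-0.42 ± 0.11) and MYB34 (-0.68 ± 0.19) were lower (4 of 12 members were lower and 8 did not pass). A median of -0.21 gave camera adjusted p = 1.2e-04, and adjusted p = 0.228 with an estimated correlation, with 5 lower and 1 higher adjusted over the list alone. Of the 13 flavonoid genes 4 were higher and 9 did not pass. At median 0.28, camera gave adjusted p = 4.8e-04 (adjusted p = 0.290 with an estimated correlation), and 4 higher were counted adjusted over the list alone. No member of the salicylic acid list passed, although the list as a set was lower, with NPR1 at -0.23 ± 0.09, not passing. The median was -0.18, with no member passing adjusted over the list alone (camera adjusted p = 0.00273, adjusted p = 0.348 with an estimated correlation). Other sets were lower too, by camera with the preset correlation but not with an estimated one: ERF (-0.62), touch (-0.58) and, by a median nearer 0, pattern recognition genes. The lower calls of JAZ (-0.26), JA biosynthesis, WRKY and photosynthesis genes were lost with the processed signals, where the photosynthesis list changed direction, and that of JAZ also with slide as a block. In all 1100 genes passed (n = 2 per genotype), 708 higher and 392 lower, 71 of them by 2-fold or more. This count was unstable: it was 183 without Col-0 sample 2, 4453 with the processed signals and 56 in a fit to these 4 samples alone. The share of higher genes among those called was 64.4%, against 53.2% with the processed signals and 54.4% with quantile normalization.

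At 3 h after inoculation the vegetative storage protein genes VSP1 (3.85 ± 0.48) and VSP2 (3.69 ± 0.46), markers of the MYC2 branch of JA signalling, were higher in elp2 than in Col-0, with MYC2 (1.47 ± 0.17) and CLH1 (2.13 ± 0.21), and 6 of 9 members were higher and 3 did not pass. The median was 0.61, with 6 higher adjusted over the list alone (camera adjusted p = 3.6e-05, adjusted p = 0.113 with an estimated correlation). JA synthesis genes AOS (1.26 ± 0.14), OPR3 (1.2 ± 0.15) and AOC1 (1.29 ± 0.19) were higher (8 of 13 members were higher and 5 did not pass). With 8 higher adjusted over the list alone, the median was 0.55 (camera adjusted p = 2.1e-05, and adjusted p = 0.228 with an estimated correlation). JAZ genes followed, with JAZ10 (1.28 ± 0.21) and JAZ9 (1.17 ± 0.20), and 9 of 11 members were higher and 2 did not pass. A median of 0.60 gave camera adjusted p = 4.6e-05, and adjusted p = 0.232 with an estimated correlation, with 9 higher adjusted over the list alone. These medians rested more on slide 1 (2 arrays) than on slide 2 (1 array), at 1.1 and 0.31 for the MYC2 branch, 0.62 and 0.18 for JA synthesis and 0.67 and 0.28 for JAZ genes. The defensin genes PDF1.2A (-2.49 ± 0.37) and PDF1.2C (-2.20 ± 0.37), outputs of the branch that JA shares with ethylene, were lower, as was the chitin-binding protein gene PR4 (-1.45 ± 0.24), and 5 of 8 members were lower, 2 were higher and 1 did not pass. At median -1.70, camera gave adjusted p = 0.00956 (adjusted p = 0.30 with an estimated correlation), and 5 lower and 2 higher were counted adjusted over the list alone. Aliphatic glucosinolate genes MYB29 (1.03 ± 0.15) and BCAT4 (1.29 ± 0.20) were higher (11 of 13 members were higher, 1 was lower and 1 did not pass). The median was 0.76, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.9e-05, adjusted p = 0.327 with an estimated correlation). The epidermis and cuticle list (median 0.41, 9 of 10 members were higher and 1 did not pass) and the cell division list (median 0.30, 9 of 10 members were higher and 1 did not pass) were higher as well (camera adjusted p = 5.6e-04 and 0.00126, or 0.209 and 0.293 with an estimated correlation). The desaturase gene ADS1 (3.65 ± 0.58, well above background in 2 of 3 Col-0 samples) and AT14A (3.53 ± 0.46) and CSLA01 (3.14 ± 0.49, well above background in 2 of 3 Col-0 samples) were higher, and the ferritin gene FER1 (-3.88 ± 0.46), PCR1 (-3.01 ± 0.44) and AACT1 (-2.61 ± 0.33) and the glucanase gene BG3 (-2.32 ± 0.39) were lower. The count was 7114 genes, 4001 higher and 3113 lower, 496 of them by 2-fold or more. With slide as a block 7009 passed, and 5542 within the slide that held 2 of the 3 arrays. Leaving out single samples gave 4497 to 7650.

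At 3 h after wounding, genes higher in elp2 than in Col-0 were ADS1 (3.91 ± 0.58), PAP1 (3.29 ± 0.33), AGL19 (3.23 ± 0.48) and MRD1 (3.15 ± 0.41), where PAP1 (AT1G56650) is a regulator of anthocyanin synthesis and AGL19 a flowering regulator, and lower were BT2 (-3.26 ± 0.23), FER1 (-3.08 ± 0.46), NAP (-2.71 ± 0.14) and SEN1 (-2.22 ± 0.23). JA synthesis genes OPR3 (1.35 ± 0.15) and AOC2 (1.26 ± 0.14) were higher (10 of 13 members were higher and 3 did not pass). The median was 0.61, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.5e-04, adjusted p = 0.273 with an estimated correlation). Aliphatic glucosinolate genes FMO_GS-OX1 (1.73 ± 0.16) and MYB29 (1.47 ± 0.15) were higher (12 of 13 members were higher and 1 did not pass). With 12 higher adjusted over the list alone, the median was 1.11 (camera adjusted p = 3.6e-07, and adjusted p = 0.232 with an estimated correlation). WRKY genes WRKY26 (-1.47 ± 0.10) and WRKY25 (-1.1 ± 0.12) were lower (13 of 20 members were lower, 1 was higher and 6 did not pass). A median of -0.55 gave camera adjusted p = 3.3e-06, and adjusted p = 0.113 with an estimated correlation, with 13 lower and 1 higher adjusted over the list alone. The senescence list was lower, with NAC092 (-1.51 ± 0.18) and NYC1 (-1.35 ± 0.20), and 6 of 9 members were lower and 3 did not pass. At median -0.43, camera gave adjusted p = 0.00112 (adjusted p = 0.219 with an estimated correlation), and 6 lower were counted adjusted over the list alone. Salicylic acid regulators CBP60G (-1.33 ± 0.14) and SARD1 (-1.11 ± 0.15) were lower (9 of 21 members were lower and 12 did not pass). The median was -0.28, with 10 lower adjusted over the list alone (camera adjusted p = 5.8e-04, adjusted p = 0.306 with an estimated correlation). In all 9266 genes passed, 5208 higher and 4058 lower, 644 by 2-fold or more. The 3 arrays lay on 1 slide, within which the count was 7516.

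Of the 7 conditions, the genotypes differed by the largest count of genes at 6 h after inoculation, 11083 of 21010, and 858 genes were lower in elp2 by 2-fold or more against 315 higher. Early regulators of defence were among the lower genes. Of 13 ERF factors 12 were lower and 1 did not pass, with ERF6 (-2.36 ± 0.23), ERF5 (-2.28 ± 0.23), ERF104 (-2.35 ± 0.25) and ERF1 (-1.94 ± 0.20). The median was -1.5, with 12 lower adjusted over the list alone (camera adjusted p = 3.6e-07, adjusted p = 0.208 with an estimated correlation). Of 20 WRKY factors 17 were lower, 1 was higher and 2 did not pass, with WRKY33 (-1.69 ± 0.16), WRKY26 (-1.51 ± 0.10) and WRKY15 (-1.2 ± 0.09); WRKY33 is needed for resistance to this fungus. With 17 lower and 1 higher adjusted over the list alone, the median was -1.08 (camera adjusted p = 4.1e-08, and adjusted p = 0.0729 with an estimated correlation). In the pattern recognition list 18 of 24 members were lower, 2 were higher and 4 did not pass, with the receptor kinase partner BIK1 (-0.84 ± 0.08), the kinase gene MPK3 (-0.90 ± 0.09) and the elicitor peptide precursor gene PROPEP3 (-1.90 ± 0.20). A median of -0.67 gave camera adjusted p = 4.1e-06, and adjusted p = 0.219 with an estimated correlation, with 20 lower and 2 higher adjusted over the list alone. Touch response genes ZAT10 (-2.66 ± 0.25), CML37 (-2.52 ± 0.18) and ZAT12 (-2.24 ± 0.32) were lower (10 of 11 members were lower and 1 did not pass). At median -1.71, camera gave adjusted p = 5.7e-05 (adjusted p = 0.248 with an estimated correlation), and 10 lower and 1 higher were counted adjusted over the list alone. Genes of indole compounds were lower as well, with MYB51 (-2.07 ± 0.13), CYP81F2 (-2.35 ± 0.20) and IGMT2 (-1.97 ± 0.16) of the indole glucosinolate list (10 of 12 members were lower, 1 was higher and 1 did not pass). The median was -0.88, with 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 5.8e-06, adjusted p = 0.170 with an estimated correlation). In the tryptophan and camalexin list 9 of 13 members were lower and 4 did not pass, with CYP79B2 (-1.32 ± 0.16) and TSA1 (-1.13 ± 0.13). The median was -0.97, with 9 lower adjusted over the list alone (camera adjusted p = 8.7e-05, adjusted p = 0.290 with an estimated correlation). Detoxification genes GSTU10 (-1.67 ± 0.22) and GSTU3 (-1.56 ± 0.24) were lower (16 of 22 members were lower and 6 did not pass). With 19 lower adjusted over the list alone, the median was -0.89 (camera adjusted p = 1.2e-05, and adjusted p = 0.352 with an estimated correlation).

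Highest in elp2 against Col-0 at 6 h were ADS1 (5.02 ± 0.58), MRD1 (4.35 ± 0.41) and AGL19 (4.19 ± 0.48) and the iron deficiency regulators BHLH100 (3.65 ± 0.40) and bHLH38 (3.57 ± 0.50). The lowest were DMP1 (-3.43 ± 0.24), LTP4 (-3.39 ± 0.65), PCR1 (-3.25 ± 0.44), PDF1.2A (-3.23 ± 0.37) and IAR3 (-3.18 ± 0.25), where IAR3 splits amino acid conjugates of auxin and JA. Photosynthesis genes GAPA (0.75 ± 0.09) and PSBO2 (0.65 ± 0.09) were higher (23 of 33 members were higher and 10 did not pass). A median of 0.32 gave camera adjusted p = 1.9e-04, and adjusted p = 0.343 with an estimated correlation, with 23 higher adjusted over the list alone. Cell division genes KNOLLE (0.75 ± 0.09) and CDKB1;1 (0.65 ± 0.10) were higher (7 of 10 members were higher and 3 did not pass). At median 0.57, camera gave adjusted p = 0.00188 (adjusted p = 0.315 with an estimated correlation), and 7 higher were counted adjusted over the list alone. Epidermal genes FDH (0.97 ± 0.10) and ATML1 (0.72 ± 0.09) were higher as well (7 of 10 members were higher and 3 did not pass). The median was 0.58, with 7 higher adjusted over the list alone (camera adjusted p = 0.00268, adjusted p = 0.240 with an estimated correlation). Guard cell genes were mostly higher, with TGG1 (0.99 ± 0.18) and SLAC1 (0.53 ± 0.10), while the potassium channel gene KAT1 (-0.71 ± 0.08) was lower (7 of 8 members were higher and 1 was lower). The median was 0.45, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0362, adjusted p = 0.371 with an estimated correlation). Of the 7 vascular genes 3 were higher, 2 were lower and 2 did not pass. The list did not pass as a set (median -0.11, 3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.828, adjusted p = 0.890 with an estimated correlation). The 3 arrays lay on 1 slide, within which 11426 genes passed.

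**Figure D3:**
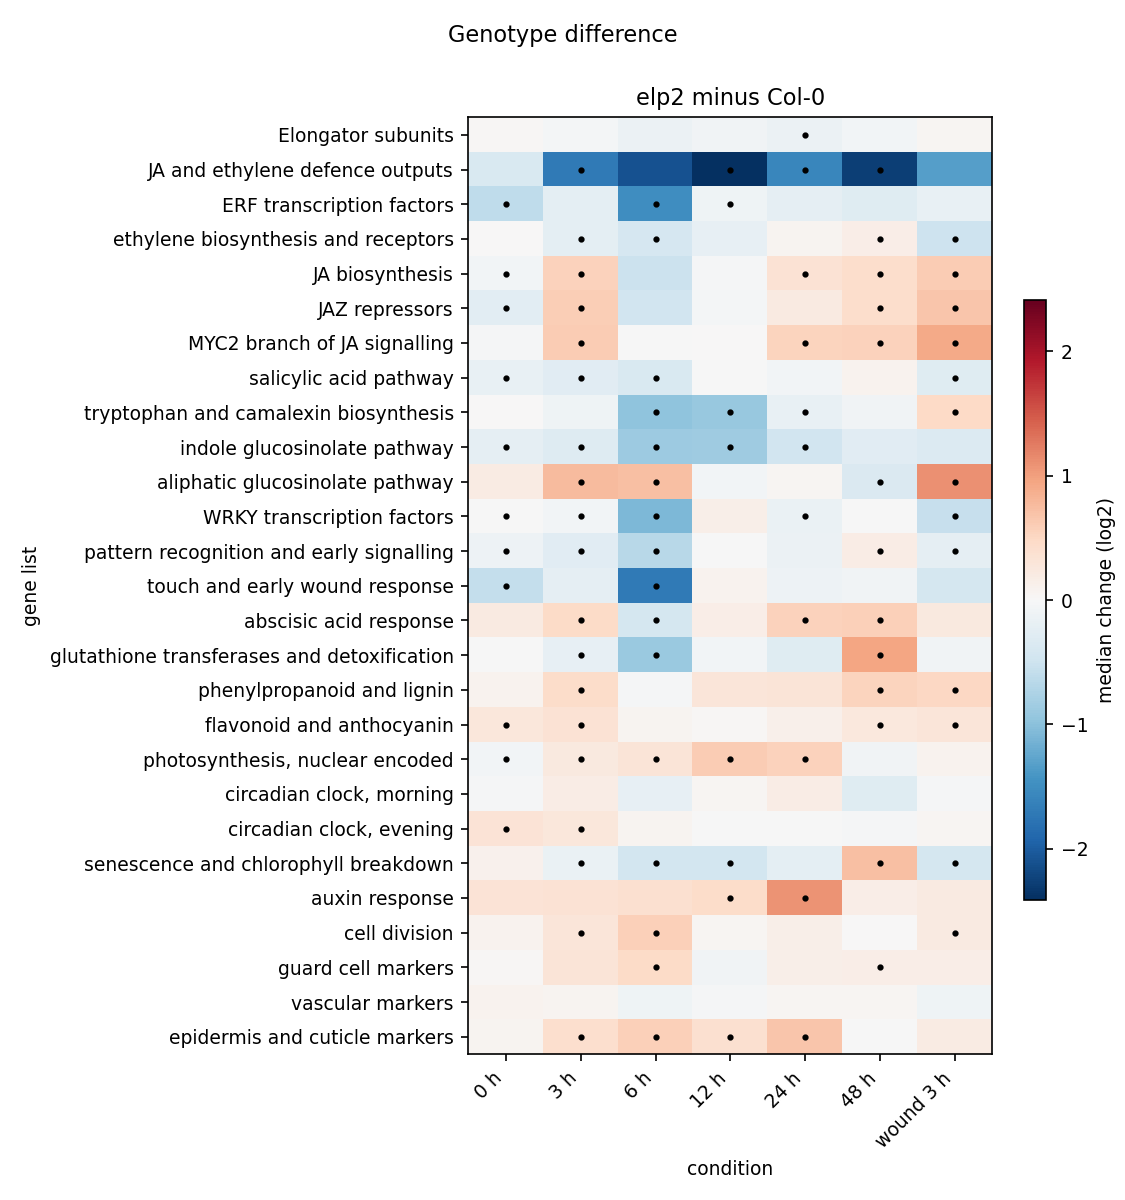
Median log2 difference between elp2 and Col-0 (colour) of the 27 gene lists in each of the 7 conditions; a dot marks lists that passed the camera test at adjusted p 0.05 with the preset correlation. The WRKY list lies at -1.08 at 6 h and at 0.13 at 12 h.

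At 12 h the defensins were among the genes most reduced in elp2: PDF1.2A (-3.70 ± 0.37), PDF1.2B (-3.24 ± 0.37), PDF1.2C (-3.13 ± 0.37) and PDF1.3 (-2.97 ± 0.38), again with signal that may be shared, and their regulator ORA59 (-1.85 ± 0.27) was lower. Of the defence outputs 6 were lower and 2 did not pass. With 6 lower adjusted over the list alone, the median was -2.41 (camera adjusted p = 3.6e-07, and adjusted p = 0.0730 with an estimated correlation). The tryptophan and camalexin list was lower, with TSA1 (-1.68 ± 0.13) and TSB1 (-1.33 ± 0.12) and PAT1 (-1.2 ± 0.09), both in tryptophan synthesis (10 of 13 members were lower and 3 did not pass). A median of -0.91 gave camera adjusted p = 2.4e-10, and adjusted p = 0.117 with an estimated correlation, with 10 lower adjusted over the list alone. Indole glucosinolate genes UGT74B1 (-1.45 ± 0.07) and CYP83B1 (-1.27 ± 0.12) were lower (8 of 12 members were lower, 1 was higher and 3 did not pass). At median -0.85, camera gave adjusted p = 8.5e-07 (adjusted p = 0.143 with an estimated correlation), and 8 lower and 1 higher were counted adjusted over the list alone. Photosynthesis genes were higher, with LHCB3 (1.37 ± 0.14), PSBO2 (0.95 ± 0.09) and GAPB (0.92 ± 0.10), and 26 of 33 members were higher and 7 did not pass. The median was 0.61, with 28 higher adjusted over the list alone (camera adjusted p = 2.9e-19, adjusted p = 0.0426 with an estimated correlation). Of the WRKY genes, mostly lower at 6 h, 6 were higher, 2 were lower and 12 did not pass at 12 h. The list did not pass as a set (median 0.13, 8 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.219, adjusted p = 0.631 with an estimated correlation). Further higher genes were AGL19 (2.45 ± 0.48), GER3 (2.02 ± 0.51) and ARR7 (2.01 ± 0.19), the last a response regulator of cytokinin signalling, and IAR3 (-3.14 ± 0.25) was again lower. The count was 5675 genes, 3006 higher and 2669 lower, 221 by 2-fold or more. The 3 arrays lay on 1 slide, within which it was 3546, and it was 3251 to 5964 with single samples left out and 9167 with the processed signals.

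At 24 h the salicylic acid methyltransferase gene BSMT1 (4.58 ± 0.51) was the highest in elp2, ahead of ADS1 (3.84 ± 0.58), AT14A (3.42 ± 0.46), MBP1 (3.40 ± 0.42) and AGL19 (3.06 ± 0.48). The defensins PDF1.2C (-2.40 ± 0.37) and PDF1.2A (-2.22 ± 0.37) stayed lower, and so did PCR1 (-3.19 ± 0.44) and IAR3 (-2.62 ± 0.25) and the amidohydrolase gene ILL5 (-2.53 ± 0.21). Of the defence outputs 7 were lower and 1 was higher. The median was -1.57, with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.3e-04, adjusted p = 0.170 with an estimated correlation). The JA marker genes VSP2 (3.00 ± 0.46), VSP1 (2.81 ± 0.48) and TAT3 (2.3 ± 0.39) were higher (4 of 9 members were higher, 1 was lower and 4 did not pass). With 4 higher and 1 lower adjusted over the list alone, the median was 0.54 (camera adjusted p = 0.0325, and adjusted p = 0.345 with an estimated correlation). Auxin-induced genes IAA5 (1.59 ± 0.21), IAA19 (1.24 ± 0.17) and IAA1 (1.19 ± 0.09) were higher (8 of 9 members were higher and 1 did not pass). A median of 1.08 gave camera adjusted p = 9.4e-06, and adjusted p = 0.170 with an estimated correlation, with 8 higher adjusted over the list alone. The auxin median was 1.52 on slide 3 (1 array) and 0.82 on slide 4 (2 arrays). Photosynthesis genes LHCB2.3 (1.92 ± 0.26) and LHCB2.1 (0.99 ± 0.11) were higher (26 of 33 members were higher and 7 did not pass). At median 0.55, camera gave adjusted p = 1.2e-11 (adjusted p = 0.119 with an estimated correlation), and 28 higher were counted adjusted over the list alone. The abscisic acid response list was higher, with KIN1 (1.22 ± 0.25) and RD22 (1.12 ± 0.14), and 8 of 13 members were higher and 5 did not pass. The median was 0.56, with 10 higher adjusted over the list alone (camera adjusted p = 0.00373, adjusted p = 0.345 with an estimated correlation). Epidermis and cuticle markers were higher too, at a median of 0.66 (8 of 10 members were higher and 2 did not pass; camera adjusted p = 1.0e-04, or 0.159 with an estimated correlation). The count was 7710 genes, 4546 higher and 3164 lower, 396 by 2-fold or more. With slide as a block it was 7708, and 5466 within the slide that held 2 of the 3 arrays.

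At 48 h the anthocyanin regulator PAP1 (AT1G56650, 3.78 ± 0.33), DXPS1 (3.03 ± 0.30), SWEET15 (2.90 ± 0.33), VSP1 (2.82 ± 0.48) and MSRB7 (2.79 ± 0.17) were the highest in elp2. The lowest were PDF1.2C (-2.53 ± 0.37), LTL1 (-2.53 ± 0.27), PDF1.3 (-2.49 ± 0.38), PDF1.2B (-2.48 ± 0.37) and PDF1.2A (-2.40 ± 0.37), and of the defence outputs 6 were lower and 2 did not pass. The median was -2.26, with 6 lower adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.113 with an estimated correlation). Detoxification genes, lower at 6 h, were now higher, with GSTU19 (1.14 ± 0.15), GSTU11 (1.59 ± 0.26) and AOX1A (0.93 ± 0.14), and 15 of 22 members were higher and 7 did not pass. With 17 higher adjusted over the list alone, the median was 0.95 (camera adjusted p = 1.9e-09, and adjusted p = 0.235 with an estimated correlation). Phenylpropanoid genes CCOAOMT1 (1.01 ± 0.10) and PAL1 (0.94 ± 0.18) were higher (10 of 12 members were higher and 2 did not pass). A median of 0.54 gave camera adjusted p = 1.1e-06, and adjusted p = 0.170 with an estimated correlation, with 11 higher adjusted over the list alone. JA synthesis genes LOX2 (1.26 ± 0.25) and ACX1 (0.98 ± 0.11) were higher (6 of 13 members were higher and 7 did not pass). At median 0.42, camera gave adjusted p = 3.2e-05 (adjusted p = 0.232 with an estimated correlation), and 9 higher were counted adjusted over the list alone. Aliphatic glucosinolate genes, higher at 3 h, were lower, with CYP79F1 (-1.40 ± 0.19) and MAM1 (-1.08 ± 0.21), and 5 of 13 members were lower and 8 did not pass. The median was -0.35, with 7 lower adjusted over the list alone (camera adjusted p = 0.00233, adjusted p = 0.441 with an estimated correlation). Senescence genes SAG13 (1.33 ± 0.26) and SGR1 (0.73 ± 0.11) were higher (6 of 9 members were higher, 1 was lower and 2 did not pass). The median was 0.72, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.4e-04, adjusted p = 0.208 with an estimated correlation). The count was 4858 genes, 2199 higher and 2659 lower, 352 by 2-fold or more. Modelling slide gave 4719, 2908 came from the slide that held 2 of the 3 arrays, and 9202 with the processed signals.

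Averaged over the 7 conditions, 12956 genes differed, 7218 higher and 5738 lower in elp2, but 136 by 2-fold or more. Among the genes highest on average, with the same sign on all 20 arrays, were AGL19 (2.86 ± 0.20), MRD1 (2.48 ± 0.17), VSP2 (2.21 ± 0.19) and VSP1 (2.21 ± 0.20) and PAP1 (2.05 ± 0.13). Among the lowest, also with the same sign on all 20 arrays, were PDF1.2A (-2.37 ± 0.15), PCR1 (-2.14 ± 0.18) and PDF1.2B (-2.14 ± 0.15). None of these genes passed in each of the 7 conditions. Indole glucosinolate genes were lower, with MYB51 (-1.01 ± 0.05), IGMT1 (-0.92 ± 0.06) and SOT16 (-0.56 ± 0.04), and 10 of 12 members were lower, 1 was higher and 1 did not pass. With 10 lower and 1 higher adjusted over the list alone, the median was -0.54 (camera adjusted p = 1.8e-05, and adjusted p = 0.193 with an estimated correlation). Auxin genes IAA5 (0.89 ± 0.09) and IAA6 (0.76 ± 0.09) were higher (7 of 9 members were higher and 2 did not pass). A median of 0.46 gave camera adjusted p = 0.00349, and adjusted p = 0.327 with an estimated correlation, with 7 higher adjusted over the list alone. Epidermal genes LTP1 (0.91 ± 0.06) and FDH (0.50 ± 0.04) were higher (9 of 10 members were higher and 1 did not pass). At median 0.31, camera gave adjusted p = 9.1e-04 (adjusted p = 0.220 with an estimated correlation), and 9 higher were counted adjusted over the list alone. Of the 5 morning clock genes 1 was lower and 4 did not pass. The list did not pass as a set (median 0.01, 1 lower adjusted over the list alone, camera adjusted p = 0.603, adjusted p = 0.811 with an estimated correlation).

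Whether the response itself differed between genotypes was tested by the difference of the 2 responses, which share the 0 h samples across times. A difference at 0 h, where n = 2 per genotype, enters each value. The counts were unstable: with single samples left out they were 264 to 2609 at 3 h (other ranges below). At 3 h 966 genes passed. The JA genes MYC2 (2.18 ± 0.27), OPR3 (1.67 ± 0.24) and JAZ10 (1.72 ± 0.34) were among those with higher responses in elp2. They had a lower start at 0 h (-0.71 ± 0.21 for MYC2, -0.47 ± 0.19, not passing, for OPR3 and -0.43 ± 0.26, not passing, for JAZ10). The response of FER1 (-3.68 ± 0.72) and BT2 (-3.56 ± 0.36) was lower. For the MYC2 branch, at -0.03 at 0 h, 5 of 9 members were higher and 4 did not pass. The median was 1.40, with 7 higher adjusted over the list alone (camera adjusted p = 6.3e-08, adjusted p = 0.0337 with an estimated correlation). At 6 h 5472 genes passed, 2249 higher and 3223 lower (41.1% higher, against 54.9% with the processed signals and 55.4% with quantile normalization). The rises of WRKY26 (-1.33 ± 0.16), ERF1 (-1.85 ± 0.32) and MYB51 (-1.93 ± 0.20) were smaller in elp2, and the response of BHLH100 (3.59 ± 0.64) was higher. BT2, whose 0 h level was higher in elp2 (2.64 ± 0.28), had a lower response (-4.69 ± 0.36). Of the WRKY list 13 were lower and 7 did not pass. The median was -0.87, with 13 lower adjusted over the list alone (camera adjusted p = 7.6e-07, adjusted p = 0.10 with an estimated correlation). At 12 h, with 1744 genes, TSB1 (-1.56 ± 0.18) rose less in elp2 and LHCB3 (1.44 ± 0.23) fell less. The value of PDF1.2A was -3.05 ± 0.59, but PDF1.2A was not well above background in either elp2 sample at 0 h and the processed signals gave 1.02, not passing, so this difference is undecided. In the photosynthesis list 23 of 33 members were higher and 10 did not pass. With 26 higher adjusted over the list alone, the median was 0.73 (camera adjusted p = 2.7e-27, and adjusted p = 0.0150 with an estimated correlation). Of the camalexin list 9 were lower and 4 did not pass. A median of -1.11 gave camera adjusted p = 4.2e-11, and adjusted p = 0.108 with an estimated correlation, with 9 lower adjusted over the list alone. At 24 h (2979 genes) the responses of BSMT1 (4.60 ± 0.80) and TAT3 (3.08 ± 0.61) were higher, with BSMT1 well above background in 1 of 2 samples of each genotype at 0 h, and that of BT2 (-3.91 ± 0.36) lower, while PDF1.2B (-2.19 ± 0.61) changed sign with the processed signals (1.37, not passing). At 48 h (1964 genes, 36.7% higher, against 47.7% with the processed signals and 47.5% with quantile normalization) the response of MSRB7 (2.93 ± 0.26) was higher and that of LTL1 (-2.94 ± 0.43) lower, with LTL1 well above background in 1 of 2 elp2 samples at 0 h. Of the detoxification list 7 were higher and 15 did not pass. At median 1.01, camera gave adjusted p = 1.2e-11 (adjusted p = 0.208 with an estimated correlation), and 16 higher were counted adjusted over the list alone. Between inoculated and wounded leaves at 3 h, 1993 genes passed, with PAD3 (-2.17 ± 0.51) and AACT1 (-2.10 ± 0.46) lower and BT2 (2.33 ± 0.32) and WRKY28 (0.94 ± 0.15) higher in elp2, where BT2 and WRKY28 were lower and PAD3 higher than in Col-0 after wounding (-3.26 ± 0.23, -0.99 ± 0.11 and 0.97 ± 0.36).

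The size of the whole response was compared through the slope of the difference of the 2 responses on their mean, over genes whose mean response passed and was 2-fold or more. At 6 h the elp2 response was 0.778 of the Col-0 response over 2715 genes, and leaving out single samples moved it between 0.755 and 0.802. Risen genes gave 0.718 and fallen genes 0.908 at 6 h, but at the other times risen genes had the higher ratio (0.922 and 0.847 at 3 h, 0.906 and 0.887 at 12 h, 0.928 and 0.799 at 24 h, 1.1 and 1.05 at 48 h). The ratio was 0.906 at 3 h, 0.897 at 12 h, 0.881 at 24 h and 1.08 at 48 h. With the processed signals these 5 ratios, in order of time, were 0.944, 0.850, 0.931, 0.916 and 1.08. No test across genes was made of them, since genes are not independent replicates.

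**Figure D4:**
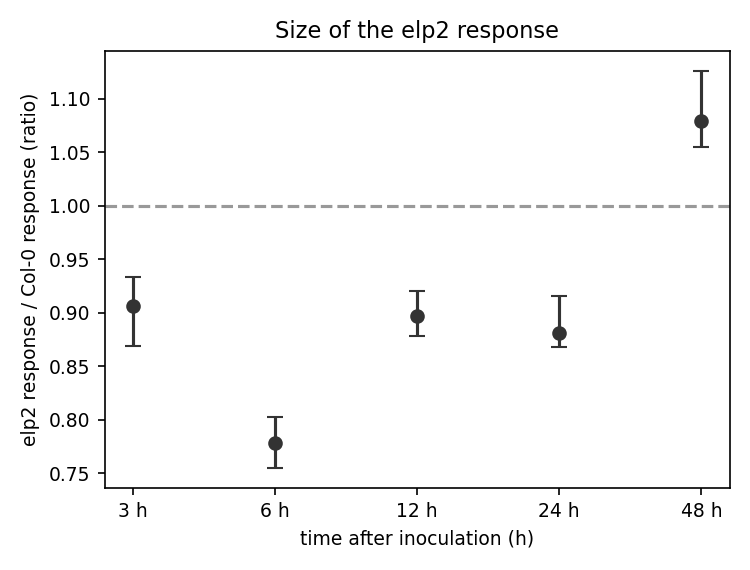
Ratio of the elp2 response to the Col-0 response (log2 change from 0 h) at each time after inoculation, evenly spaced; bars from below to above each point span the values with single samples left out. The ratio lies at 0.778 at 6 h and at 1.08 at 48 h, and the dashed line marks equal responses.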

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

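The comparisons of responses and the regrouping of samples were planned before the results were seen, while the tests of another collection hour, a slower response, infection and wounding below were chosen after seeing the result. A difference between groups was what marked 6 results: the response differed between elp2 and Col-0 for 966 genes at 3 h, 5472 at 6 h, 1744 at 12 h, 2979 at 24 h, 1964 at 48 h and 1993 between inoculated and wounded leaves. When the 3 and 3 samples of a condition were regrouped in the other 9 ways, at most 11 genes were called at 6 h, 34 at 24 h, 53 at 48 h, 640 at 12 h, 1094 after wounding and 1935 at 3 h, below the real counts. Of 10 groupings, 4 split each array pair, too few for a share under 0.05. For inoculated against wounded leaves, the highest other counts were 532 in Col-0, 128 in elp2 and 814 for the difference of responses, again of 10 groupings each. For the mean over the 7 conditions, the real one of 100 groupings gave 12956 genes and the next 1131. Chance between plants stays open if samples are pools.

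The ERF, WRKY, pattern recognition and touch genes were lower in elp2 at 6 h, with a median of -1.11 over 68 genes. Dye bias was excluded by medians of -1.09, -0.94 and -1.04 on the 3 arrays with both dye orientations. Processed signals gave -1.08 but may share normalization error. Collection under 3 h apart stays open: 16 clock genes differed between genotypes by 0.149 of their change in Col-0 from 3 to 6 h. A slower response of elp2 stays open: the median was back at 0.0153 at 12 h, but it was only -0.23 at 3 h, where the lists had risen by 1.02 in Col-0 and 1.1 in elp2, against 0.94 and 0.41 at 6 h. A late start and a shorter or weaker response cannot be told apart, and ERF and touch lists were lower at 0 h.

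Evening clock genes were lower at 24 and 48 h than at 0 h, with a median of -1.73 in Col-0 and -2.00 in elp2 at 24 h. Slide stays open: differences between slides within a condition were at most 0.0879, but no condition links the slide of the 0 h leaves to those of the 24 and 48 h leaves, so that bound does not reach this comparison. If 0 h leaves had been taken at another hour of the day, the 24 and 48 h leaves should be alike, but they differed by 0.30 in Col-0 and 0.28 in elp2, between the bounds set, so this stays open. Infection could not be tested, as no uninoculated leaves were taken at these times. At 3 h the inoculated minus wounded median was -0.0901 in Col-0.

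Tryptophan and camalexin genes were higher in inoculated than in wounded leaves at 3 h, with a median of 0.54 in Col-0 and 0.42 in elp2. More wounding of the inoculated leaves stays open: the touch gene median was -0.63 in Col-0 and -0.45 in elp2, but most of these genes did not pass, and within a condition the list differed between slides by up to 0.671. Slide cannot be excluded either: within a condition the camalexin list differed between slides by up to 0.393, and the 2 treatments share no slide.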

How the results depend on the processing

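The tests within slides, with slide as a random block and with the pairing by array at 0 h, and the list tests with slide as a block or no array block, were chosen after seeing the result, and the other alternatives before it. Of the counts and ratios under the alternatives, 469 stayed within 1.5 times, or for the ratios within the range, of the value given, and 93 did not. The cause was not tested unless named. With the processed signals and with quantile normalization, the genotype counts at 0, 12 and 48 h rose from 1100, 5675 and 4858 to 4453, 9167 and 9202, and to 3805, 8877 and 8552. The differing responses at 3, 12, 24 and 48 h rose from 966, 1744, 2979 and 1964 to 2799, 4902, 5378 and 5424, and to 2527, 4547, 4910 and 4951. The response ratios with the processed signals were 0.944 at 3 h, 0.850 at 6 h, 0.931 at 12 h and 0.916 at 24 h. Without the dye term, 634 genes passed at 0 h, and 522, 1064 and 1221 for the responses at 3 h, 12 h and inoculated against wounded. Without the array block it was 439 at 0 h and 294, 3312, 782, 1472, 893 and 842 for the responses at 3, 6, 12, 24 and 48 h and inoculated against wounded. A random slide block gave 490, 326, 3545, 879, 1617, 961 and 927 for the same 7 counts, and 2162 in Col-0 and 641 in elp2 for inoculated minus wounded. In fits to the compared groups alone, which have fewer samples, 56, 2064 and 3550 genes passed between genotypes at 0, 3 and 12 h, 5629 in elp2 at 3 h and 6382 after wounding, 261 and 0 for inoculated minus wounded in Col-0 and elp2, and 79, 142, 1942, 887 and 381 for the responses at 3, 12, 24 and 48 h and inoculated against wounded. Within slides, which hold fewer arrays, the counts were 91 at 0 h, 40 at 3 h on slide 2, 3546 at 12 h, 1735 at 24 h on slide 3, 2908 and 491 at 48 h on slides 4 and 5, and 1637 for the response at 3 h. Those at 3 h on slide 2, at 24 h on slide 3 and at 48 h on slide 5 compare 1 sample of each genotype, with the spread taken from the other groups on the slide, and test little.

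Leaving out single samples, where a lone sample left at 0 h was assumed to vary like the others, gave 183 to 1196 genes between genotypes at 0 h, 4497 to 7650 at 3 h and 3251 to 5964 at 12 h, and 3318 to 4576 at 48 h. For inoculated minus wounded it gave 1551 to 4133 in Col-0 and 318 to 2343 in elp2. For the responses it gave 264 to 2609 at 3 h, 3372 to 5566 at 6 h, 1003 to 2342 at 12 h, 1487 to 3161 at 24 h, 897 to 2085 at 48 h and 893 to 2607 for inoculated against wounded.

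Of 756 pairs of list and contrast, 378 passed with the preset correlation and 17 with an estimated one, so most list results rest on the preset. Fry called 484, of which 355 were shared, and the processed signals 352, of which 325 were shared. With the replicate number as a block, 371 passed (365 shared), no count of genes moved by over 1.5 times (775 at 0 h and 10556 at 6 h), and of the lists described it changed no call but that of the Elongator list at 24 h. Of 18 pairs, 15 correlated best with their own number. At 0 h the numbers looked crossed, and pairing by array gave 742 genes. The series matrix was not run, because its columns and the array files disagree on labels. Signal over background limits the dim genes, which the arrays measure as bounds. The sign of 4 named genes changed: with the processed signals PDF1.2A for the response at 12 h (1.02) and PDF1.2B at 24 h (1.37), both dim in elp2 at 0 h, and with another probe TT19 (-1.03) in Col-0 and RAB18 (1.28) in elp2 at 12 h. Calls lost with the replicate number as a block were SWEET15, SOT16, MYB34 and SEP1 at 0 h and ELP4 at 24 h. FER4 in Col-0 (inoculated minus wounded), the guard cell list at 6 h and, in Col-0, the flavonoid list at 12 h and the JAZ list at 24 h lost theirs with the processed signals, and VSP1 and PAL1 at 48 h with other probes.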

Other observations

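The iron lists, the constitutive genes, the test of iron status and the nearest-time test, with samples left out, were chosen after seeing the result. Iron deficiency regulators were higher in elp2 at 6 h, with BHLH38 (3.57 ± 0.50, n = 3) and BHLH39 (3.31 ± 0.47), factors that start the uptake response, the repressor gene PYE (1.34 ± 0.19) and the ubiquitin ligase gene BTS (1.61 ± 0.22). In a list of 13 such genes, 13 were higher at 6 h (median 1.5, camera adjusted p = 9.5e-07, adjusted p = 0.349 with an estimated correlation), 12 at 3 h, 12 after wounding, 8 at 24 h, 3 at 12 h and none at 0 and 48 h. Iron storage genes went the other way at 3 h, with FER1 (-3.88 ± 0.46), a ferritin gene, and the transporter gene YSL1 (-1.15 ± 0.15), and 6 of 8 were lower (camera adjusted p = 4.7e-05, adjusted p = 0.349 with an estimated correlation). At 6 h 5 were lower, after wounding 4, at 24 h 2 and at 12 h 1 (camera adjusted p = 0.130 and 0.266 for these last times), at 48 h 1 with 1 higher, and none at 0 h. At 0 h an iron difference as large as at 6 h was excluded, but not a smaller one. The mean of 4 regulators was 0.14 (each ± 0.40 to 0.61), 0.0436 of the 3.27 at 6 h.

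Some genes differed in each of the 7 conditions, 47 higher and 63 lower in elp2. Chosen after their values were seen, examples of the higher genes are AXR3, an auxin-induced repressor, by 0.75 to 1.62, LTP1, a lipid transfer protein gene of the epidermis, by 0.56 to 1.61, and HMGA, a chromatin protein gene, by 0.55 to 1.11. Examples of the lower genes are IAR3, by -3.18 to -0.74, the metallothionein gene MT2B, by -1.88 to -0.82, and SIB1, whose product binds WRKY33, by -1.56 to -0.47. By contrast, 3527 genes were higher in 1 condition and lower in another.

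Whether elp2 leaves as a whole lagged behind Col-0 was tested by finding the Col-0 time nearest to each elp2 group over all genes. At 0 of 5 times was the nearest Col-0 group an earlier one. At 6 h the elp2 leaves lay 0.495 log2 units (root mean square) from Col-0 at 6 h and 0.516 from Col-0 at 3 h. Leaving out 1 of 3 Col-0 samples at 6 h made 3 h the nearest there, so a delay at 6 h stays open. Other times kept their nearest, but few samples enter each. On the path from the preceding Col-0 time to the same one (0 to 1), elp2 lay at 0.791, 0.572, 0.884, 0.857 and 0.853 in order of time, short of Col-0 each time. A shorter delay, a weaker response and noise in the means all lower this position and were not told apart.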
